A study of Homo sapiens with 47 samples.

How the data were processed

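The study profiled RNA contacts of CDK11, a cyclin-dependent kinase, in HEK293 Flp-in cells, a human embryonic kidney line that carries a single site for inserting a transgene. The assay was iCLIP (individual-nucleotide crosslinking and immunoprecipitation), in which UV light joins protein to RNA, the protein is pulled down, and reverse transcription stops at the joined nucleotide, so that each cDNA end marks a crosslink position. Of the 47 samples in the labels, the 14 iCLIP libraries are analysed here and the other 33, from other assays, are not analysed here. Per the labels' protocols, FLAG-tagged CDK11 was induced with doxycycline, cells were crosslinked at 254 nm (200 mJ/cm2) or, after 100 uM 4-thiouridine (4SU), at 365 nm, and the protein was precipitated with a FLAG antibody. Technical replicates of a condition were pooled, per the labels' protocols. The libraries form 7 groups of 2. They are full-length CDK11 at 254 nm, full-length CDK11 with 4SU at 365 nm, the construct labelled 1del226 under both methods, the construct labelled 226del783 with 4SU at 365 nm, full-length CDK11 without UV, and full-length CDK11 with 4SU at 365 nm without antibody. The labels do not define the 2 construct names; their protocols name cell lines of F-CDK11 and of F-CDK11 (226-783), without saying which name the second line goes with. The no-antibody group follows the sample titles, although another label field of these samples lists the antibody.

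Each deposited file lists single-nucleotide positions with a signed whole-number score. Per the file headers, the positions are in hg19 coordinates, passed a peak test with 100 permutations in a neighborhood of 15 nt at an FDR of 0.05, and were tested within regions of Ensembl release 59, separately for each library. The size of the score was read as the number of cDNAs, after the file headers, and its sign as the strand, because 21 of the 198929 listed positions occur on both signs. The submitters' processing notes name Bowtie 0.12.7, STAR 2.5.2a and SAMtools 0.1.19 for the series without saying which assay each served, and the aligner of the iCLIP reads is not given in the sources used here. Positions that did not pass the peak test are not in the lists. A list's cDNA total is therefore not its sequencing depth, which is unknown here, a position that is missing from a list is "not listed" and not zero, and a longer list can name more weak sites. The lists held from 358 to 78885 sites and from 593 to 416874 cDNAs.

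No annotation of the files' build was used, so no site was assigned to a gene, exon, intron or UTR. The histone gene share, the histone gene enrichment, the gene-level tests, the gene list tests and the intronic share that had been designed were not run. Stranded windows of 10 kb took the place of genes, and the share of cDNAs in chromosome 6 from 26 to 28 Mb took the place of the histone gene share, both set before site positions were examined. That interval holds the main histone gene cluster and also many tRNA genes, so its share is not a histone measure.

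Numbers of listed sites were compared as mean log10 values with exact two-sided permutation tests, over all 70 assignments of 8 libraries for full-length against the 4 control libraries, and within crosslinking method (36 assignments) for full-length against 1del226. Shares of cDNAs in parts of the genome were tested the same way, with Benjamini-Hochberg adjustment over 8 tests. The deposited scores are signed and were not entered as counts, although their sizes were read as numbers of cDNAs, and the design's fallback was used for windows. This was limma-trend (limma 3.58.1 in R 4.3.3) on log2(share + 1), with the share in parts of 1000000 listed cDNAs (ppm), with means of 5 groups fitted over 10 crosslinked libraries and Benjamini-Hochberg adjustment at 0.05. Log2 differences are on that scale, which makes a difference from a group with no listed site depend on the pseudocount. Windows needed a mean share of at least 100 ppm and a site in at least 2 libraries, a filter chosen after seeing the data. On simulated libraries of 656 windows for full-length against 1del226, with 200 windows changed, the fit called 12.5% of the windows changed 4-fold and 86% of those changed 16-fold, and no unchanged window. The simulated counts had a dispersion of 0.3, as many windows raised as lowered, and no peak test. The real lists lack weak sites and many windows have an empty group, so the simulation does not give their rate of false calls. Site lists were compared as the share of the shorter list with a site of the longer list within 5 nt on the same strand, with chance estimated by moving sites 1000 bp either way. Other steps used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and statsmodels 0.14.6.

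Named positions follow a rule set before the data were examined: the 10 sites with the highest mean share over the 4 full-length crosslinked libraries, among sites listed in all 4. The rule for genes in a comparison was applied to windows: among those past an adjusted p of 0.05 whose groups do not overlap, the 10 with the largest difference in each direction. Windows named outside the rule are marked as such. A further window past the threshold stays in all counts and tests and is not reported here.

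The track lines carry tags of 2 experiment series. Replicate 1 of 6 groups belongs to the earlier series and replicate 2 to the later one, and both 226del783 libraries belong to the later one. The numbers therefore pair the libraries of the 6 groups. Over 656 windows, the deviations of same-numbered libraries from their group means correlated at 0.276 to 0.404 between the 4 full-length and 1del226 groups, and at -0.02 to 0.112 between these and 226del783. Nothing in the labels says that the 2 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Alternatives covered a minimum of 5 cDNAs per site, merging of sites within 15 nt, total cDNAs, lists limited to the same number of sites (the 3362 tallest), windows of 1 kb and 100 kb, no filter, another pseudocount, another scaling, the replicate block, the experiment series as a block, and each library left out.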

Results

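The RNA contacts of tagged CDK11 were mapped by iCLIP in 14 HEK293 Flp-in libraries, 2 for each of 7 groups. Full-length CDK11 gave 25665 and 17944 listed crosslink sites after 254 nm light, and 78885 and 26054 sites after 4SU labelling and 365 nm light. These lists held 122808, 67735, 416874 and 82679 cDNAs. The 1del226 construct gave 5209 and 3775 sites at 254 nm and 15018 and 3362 sites with 4SU. The 226del783 construct, made with 4SU only, gave 15190 and 4865 sites. The controls of the full-length protein gave 1264 and 496 sites without UV and 358 and 844 sites without antibody, with between 593 and 6530 cDNAs per list. A mean of 59.3% ± 4.1 (SD, n = 4) of the full-length sites rested on a single cDNA.

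**Figure D1:**
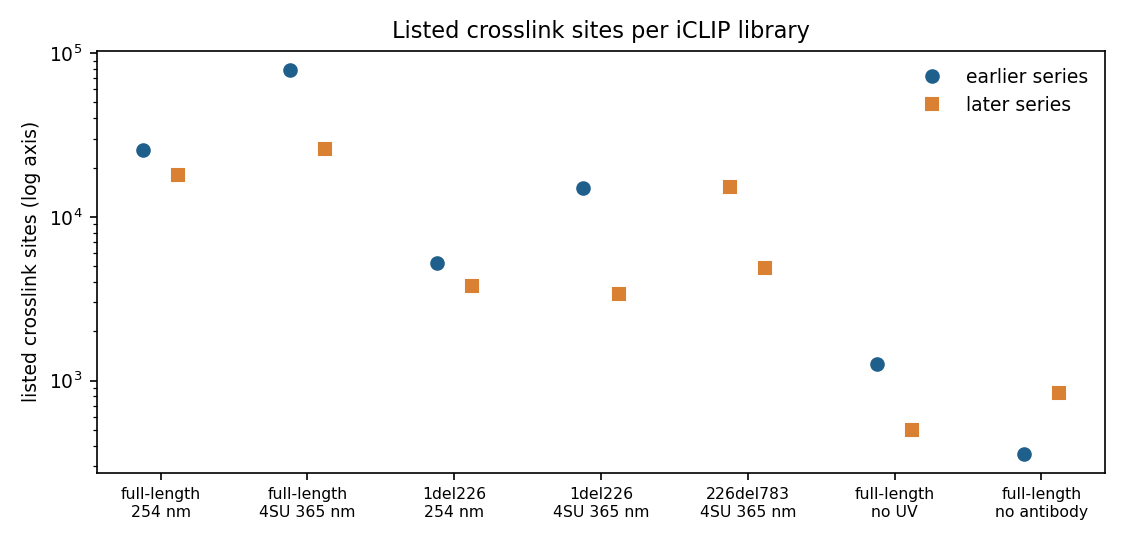
Number of listed crosslink sites in each library (log axis), by group, with circles for the earlier and squares for the later experiment series. The 4 crosslinked full-length libraries lie between 17944 and 78885 sites, and the 4 control libraries between 358 and 1264.

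The first comparison asked whether the listed sites depended on UV light and on the antibody. Crosslinked full-length CDK11 gave 47.3-fold more listed sites than the controls as a ratio of geometric means (4 against 4 libraries; exact two-sided permutation test, p = 0.0286, the smallest the design allows). With total cDNAs the ratio was 69.4, at 3.17 to 5.28 cDNAs per site in full-length lists and 1.66 to 5.17 in control lists. At 254 nm the lists were 20.3 and 36.2 times as long as the no-UV lists of the same series, and with 4SU they were 220.3 and 30.9 times as long as the no-antibody lists. When labels were exchanged only within replicate number, the replicate block, p was 0.0556, the smallest that this version allows. Lists of the controls were not random: 82.4% (range 79.0 to 86.7 over 4 pairs) of the no-UV sites lay within 5 nt of a site of a full-length 254 nm library, against 5.53% after moving the sites.

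Full-length sites recurred between libraries. Within 5 nt, 49.9% of the sites of the shorter 254 nm list were found in the other, and 57.8% for 4SU, against 4.85% and 4.45% after moving the sites. Among sites with at least 5 cDNAs these shares were 86.3% and 95.1%. Across the 2 crosslinking methods the mean was 46.6% (range 36.2 to 61.4 over 4 pairs). Of the 117360 positions listed in any full-length crosslinked library, 2745 were listed in all 4, and 1757 of those were in no control list. The control lists held only 358 to 1264 sites each, so absence from them says little.

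By amount, the full-length lists were led by a few parts of the genome. The mitochondrial chromosome, which encodes the RNAs of the respiratory chain and of mitochondrial translation, held 12.9% ± 5.06 (SD, n = 4) of the cDNAs, and contig GL000220, which carries a copy of the ribosomal RNA repeat, held 7.92% ± 8.01. Among 2669 windows of 1 Mb, averaged over both methods, these ranked first and second. With 4SU alone contig GL000220 held 2.31% and ranked 7, after chromosome 6 from 26 to 29 Mb. Over both methods chromosome 6 followed with 52 to 53 Mb (4.86% ± 3.57; 7.87% at 254 nm and 1.86%, rank 9, with 4SU), 28 to 29 Mb (4.40% ± 2.43), 27 to 28 Mb (4.32% ± 2.28) and 26 to 27 Mb (2.99% ± 1.24). The stretch of chromosome 6 from 26 to 29 Mb is known for the main cluster of histone genes and for many tRNA genes. The controls held 12.3% ± 16.0 on the mitochondrial chromosome, 10.5% ± 8.71 on contig GL000220 and 4.68% ± 1.71 on chromosome 6 from 26 to 28 Mb, where full-length CDK11 had 7.31% ± 3.47. No difference from the controls was detected in these shares (exact permutation tests, p from 0.257 to 0.971, adjusted p = 1 over 8 tests). The smallest p these tests allow is 0.0286, and 0.0556 for the tests against 1del226 among the same 8. No adjusted p of the 8 could therefore pass the threshold, and the adjusted values cannot decide whether the shares differ. Within 4SU libraries, full-length CDK11 had 10.1% ± 1.17 (SD, n = 2) in that chromosome 6 interval and the no-antibody lists had 4.35% ± 1.00, while at 254 nm full-length CDK11 had 4.56% ± 2.13 and the no-UV lists had 5.01% ± 2.71.

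**Figure D2:**
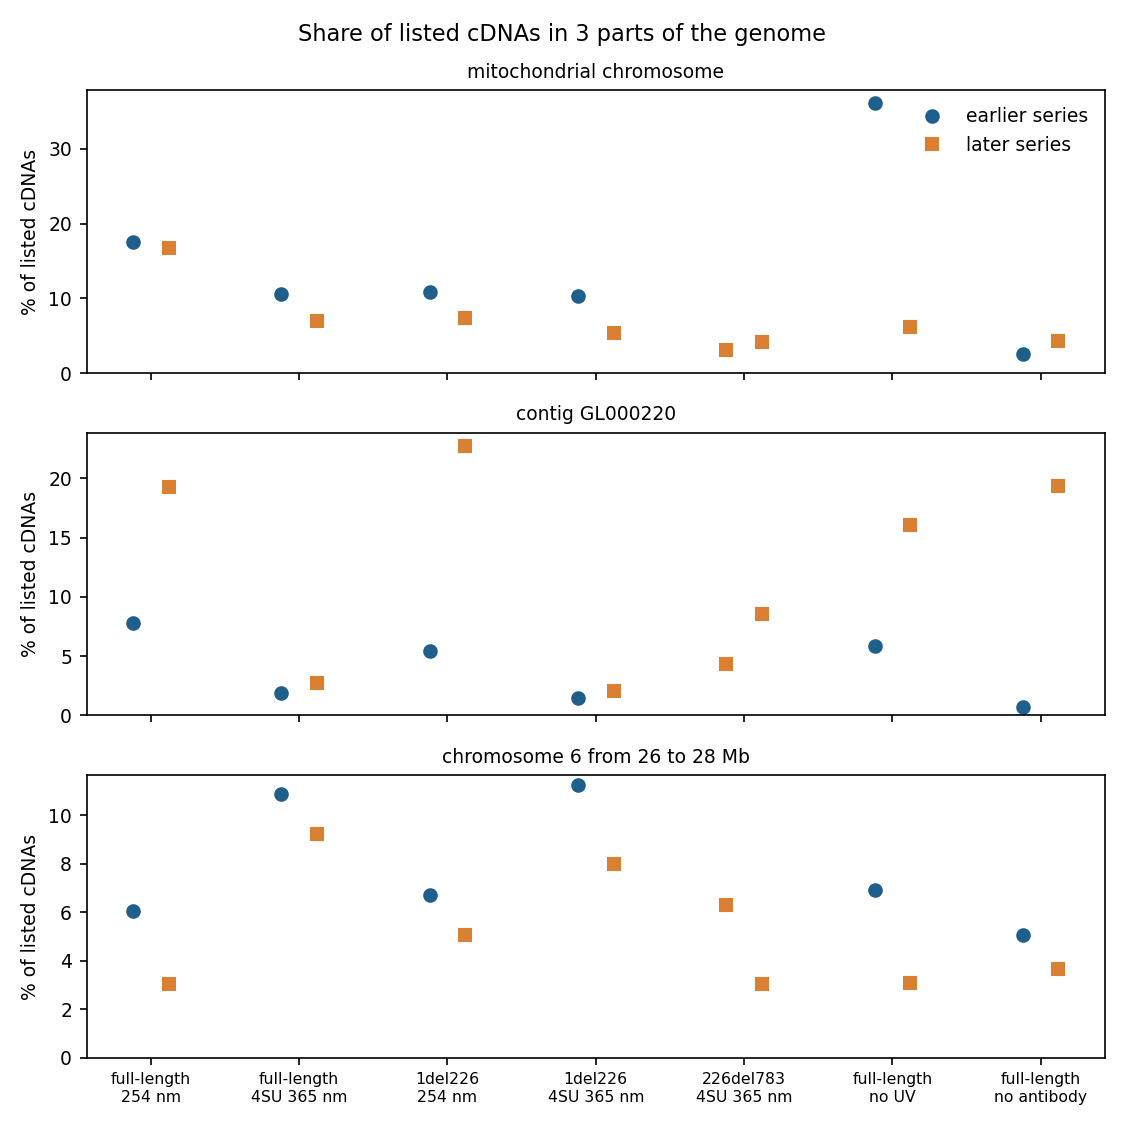
Percent of each library's listed cDNAs on the mitochondrial chromosome, on contig GL000220 and on chromosome 6 from 26 to 28 Mb, by group, with circles for the earlier and squares for the later experiment series. At 254 nm the mitochondrial share was 16.7% and 17.5% in full-length libraries and 7.41% and 10.8% for 1del226, and the no-UV libraries spread from 6.19% to 36.1% on the mitochondrial chromosome.

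The tallest sites shared by all 4 full-length libraries were also found with the other constructs. The leading position was chromosome 1, 171570091 (minus strand), with 1985 ± 1698 parts of 1000000 cDNAs (ppm; SD, n = 4), against 3435 ± 3386 for 1del226 and 1900 ± 1556 in the controls. It was followed by chromosome 6, 26575872 (plus strand; 1836 ± 1103), and by chromosome 6, 52860663 (plus strand; 1692 ± 1059), which had 997.0 ± 606.4 for 1del226 and 358.0 ± 618.1 in the controls. The others were at 58024433 on chromosome 19, 89773323 and 52860691 on chromosome 6, 139025477 on chromosome 7, 73429735 on chromosome 14, 37017952 on chromosome 17 and 180600707 on chromosome 5, with means from 1662 down to 1427 ppm. All 10 positions were listed in the 4 1del226 libraries and in both 226del783 libraries. Each was also listed in 1 to 4 of the control libraries. Most of the 10 had a higher mean share for 1del226 than for full-length CDK11, and several also had a higher mean in the controls. At 139025477 on chromosome 7 the means were 1513 ppm for full-length CDK11, 9214 for 1del226 and 2811 in the controls.

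The 1del226 construct was compared with the full-length protein under both crosslinking methods. Its lists were shorter in each of the 4 pairs of libraries that share method and series, by factors of 4.93 and 4.75 at 254 nm and 5.25 and 7.75 with 4SU. The ratio of geometric means was 5.56 (exact two-sided permutation within method, p = 0.0556, the smallest the design allows, so it cannot pass 0.05). Full-length lists held a mean of 37137 ± 28081 sites (SD, n = 4) and 1del226 lists 6841 ± 5508. The 1del226 sites were largely places where full-length CDK11 was also listed: 72.0% (range 66.6 to 82.8 over 4 pairs) at 254 nm and 75.5% (range 68.8 to 83.5) with 4SU lay within 5 nt. After moving the sites these shares were 2.84% and 1.78%. By the same measure the no-UV lists reached 82.4% at 254 nm and the no-antibody lists 65.2% with 4SU. Overlap of this size is thus reached by background and does not by itself show shared CDK11 contacts. With total cDNAs the ratio was 4.42 and p was 0.111 (exact permutation), at 3.92 to 7.01 cDNAs per site for 1del226.

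Over 656 windows of 10 kb, 20 differed in share between full-length and 1del226, with 17 higher and 3 lower in the full-length libraries (limma, adjusted p under 0.05). The median difference of all tested windows was 1.60 on the log2 scale, and 0.19 in lists of the same number of sites or 0.35 with a pseudocount of 100 ppm, so the general shift depended on both. The largest difference was on the minus strand of chromosome X, 107970001 to 107980000, with 8003 ± 7391 ppm of the cDNAs (SD, n = 4) against 2.37 ± 4.75 (log2 difference 11.55 ± 1.14 SE, limma adjusted p = 0.00661), and no control library listed it. The plus strand of chromosome 4, 20250001 to 20260000, held 1675 ± 1669 against 14.2 ± 28.5 (log2 difference 8.76 ± 1.43 SE). The minus strand of chromosome 3 from 129030001, the minus strand of chromosome 1 from 930001, and the plus strand of chromosome 12 from 860001 had 503.7 ± 270.2, 495.3 ± 224.8 and 461.1 ± 366.1 ppm in full-length libraries and were not listed for 1del226. The chromosome 3 window missed the threshold with the experiment series as a block (adjusted p = 0.0541, limma) and with each of the 8 libraries left out (adjusted p from 0.0704 to 0.163). With a pseudocount of 100 ppm 12 of the 20 windows still passed, without those from 930001 on chromosome 1 (adjusted p = 0.0506) and 860001 on chromosome 12 (adjusted p = 0.0677, limma). The rule also named windows from 34210001 (plus) and 74220001 (minus) on chromosome 6, 35650001 (minus) on chromosome 1, 40730001 (minus) on chromosome 19 and 217360001 (plus) on chromosome 2, at 250.0 to 453.3 ppm and not listed for 1del226; those from 35650001 and 40730001 missed the threshold with that pseudocount (adjusted p = 0.0748 and 0.207, limma). No control listed any of the 16 higher windows described. The control lists held only 593 to 6530 cDNAs, and 473 of the 660 windows with a site in all 4 full-length libraries were in no control. Absence from the controls was thus common and says little about these 16.

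One of the higher windows was listed in all 8 libraries, and is named after its values were seen. It lies on the plus strand of chromosome 6, 26150001 to 26160000, inside the stretch known for the main histone gene cluster, and its 290 listed positions ran from 26156551 to 26158810. It held 3734 ± 1610 ppm of the cDNAs for full-length CDK11 and 522.0 ± 534.1 for 1del226, 7.15 times as much (log2 difference 3.37 ± 0.57 SE, limma adjusted p = 0.0182), and none in the controls. The call was lost in 5 of 8 fits that left out 1 library (adjusted p up to 0.0889, limma), which were those without any 1 of the full-length libraries or without 1del226 4SU replicate 2, and with no filter (adjusted p = 0.248). Over the whole interval from 26 to 28 Mb the shares did not differ, at 7.31% ± 3.47 and 7.76% ± 2.62 (difference -0.446 percentage points, exact permutation within method, p = 0.778). The mitochondrial share was 12.9% ± 5.06 and 8.46% ± 2.58, a difference of 4.46 percentage points. It was higher in full-length libraries in 4 of 4 pairs (exact permutation, p = 0.111, adjusted p = 0.889 over 8 tests). The smallest p this test allows is 0.0556, and no adjusted p of the 8 tests could pass the threshold. By share of sites, however, the mitochondrial values were 6.59% ± 1.87 and 8.89% ± 2.90.

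The 3 windows with a lower share in full-length libraries were strong in the no-UV controls. The plus strand of chromosome 17, 73030001 to 73040000, held 0.618% ± 0.330 of the cDNAs in full-length libraries, 3.94% ± 2.99 for 1del226 and 9.61% ± 7.81 without UV (SD; n = 4, 4 and 2; log2 difference -2.60 ± 0.39 SE, limma adjusted p = 0.014). The plus strand of chromosome 15, 89870001 to 89880000, held 0.443% ± 0.219, 2.21% ± 1.44 and 22.0% ± 14.2 in the same order, and the plus strand of chromosome 6, 28840001 to 28850000, held 0.283% ± 0.032, 1.47% ± 0.743 and 3.55% ± 0.637. With lists limited to the same number of sites, the 3362 tallest, no window passed between full-length and 1del226 (limma; 38 of 506 had an unadjusted p under 0.05, smallest adjusted p = 0.101). The differences of the chromosome 17, 15 and 6 windows listed in every library of both constructs changed little, from -2.60 ± 0.39 to -2.23 ± 0.41, from -2.26 ± 0.37 to -1.91 ± 0.36, from -2.26 ± 0.40 to -1.87 ± 0.40 (chromosome 6 from 28840001) and from 3.37 ± 0.57 to 3.68 ± 0.63 (chromosome 6 from 26150001; log2 ± SE), with unadjusted p from 0.0006 to 0.002 (limma). Windows missing from some 1del226 lists fell instead. The chromosome X window from 107970001 went from 11.55 ± 1.14 to 6.56 ± 3.64 (limma adjusted p = 0.728). The chromosome 4 window from 20250001 went from 8.76 ± 1.43 to 2.31 ± 1.96 (limma adjusted p = 0.841). The count of 20 fell to 0 without full-length 254 nm replicate 2, to 9 without its replicate 1, to 13 and 7 without full-length 4SU replicate 1 and 2, and rose to 42 without 1del226 4SU replicate 1. For a difference of the construct effect between crosslinking methods, 0 windows passed (limma; 30 with an unadjusted p under 0.05).

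**Figure D3:**
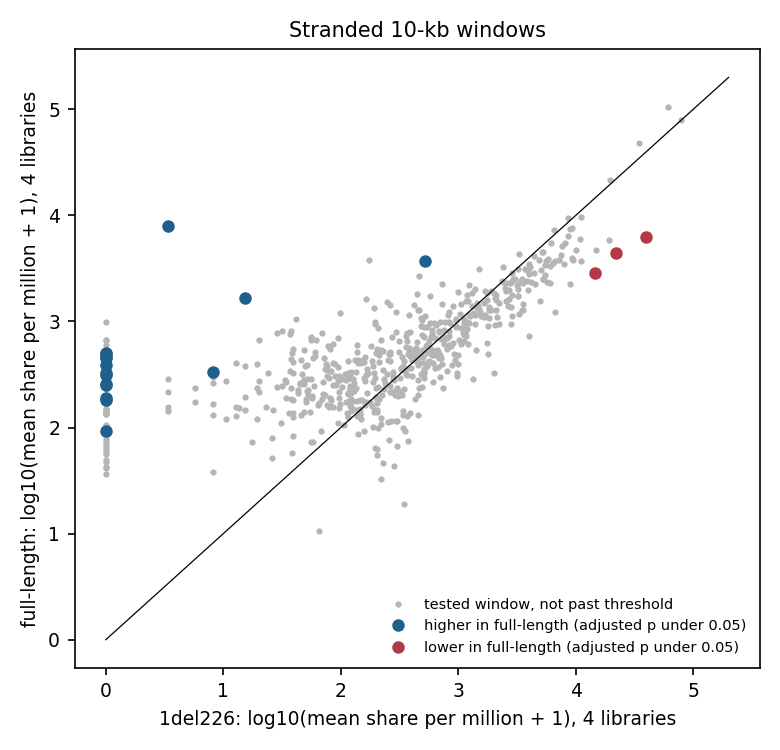
Mean share of listed cDNAs (ppm) in stranded 10-kb windows for 1del226 (x axis) and full-length CDK11 (y axis), both as log10(mean share + 1) over 4 libraries. The 16 windows higher in full-length libraries are blue, 12 of them at 0 for 1del226, the 3 lower ones are red, and the line marks equal shares.

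The 226del783 construct was compared with full-length CDK11 under 4SU and 365 nm. Its lists of 15190 and 4865 sites both come from the later series, where the full-length list had 26054 sites, 1.72 and 5.36 times as many. With 2 against 2 libraries the exact permutation test of the number of sites gave p = 0.333, the smallest it allows. A mean of 45.3% (range 42.3 to 49.5 over 4 pairs) of the sites of the shorter list lay within 5 nt of the full-length ones, and 92.5% among sites with at least 5 cDNAs. By the same measures the no-antibody lists reached 65.2% and 98.1%, the latter from only 8 and 39 sites. Such overlap does not by itself show shared CDK11 contacts. The mitochondrial chromosome held 3.61% ± 0.777 of the 226del783 cDNAs (SD, n = 2), against 8.73% ± 2.56 for full-length CDK11 with 4SU.

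In 14 of 656 windows the share was higher in full-length 4SU libraries than with 226del783, and in none was it lower (limma, adjusted p under 0.05; 117 had an unadjusted p under 0.05; median difference of all windows 2.78 on the log2 scale). In 13 of the 14 the 226del783 lists had no site, so these calls rest on the pseudocount, and 0 windows passed with a pseudocount of 100 ppm (limma; 147 with an unadjusted p under 0.05, smallest adjusted p = 0.0569) or with no filter (1125 with an unadjusted p under 0.05). They included the minus strand of chromosome 6, 27510001 to 27520000 (1317 ± 613.9 ppm, SD, n = 2), the plus strand of chromosome 15, 96320001 to 96330000 (711.9 ± 19.5), and the minus strand of chromosome 6, 26190001 to 26200000 (491.2 ± 61.8), which lies inside the histone cluster stretch. The rule further named windows from 7050001 (plus) on chromosome 12, 73510001 (minus) on chromosome 16, 61870001 and 232470001 (plus) on chromosome 2, 36900001 (minus) on chromosome 17, and 17210001 (plus) and 149660001 (minus) on chromosome 1, at 401.4 to 1606 ppm. Outside the rule for size, the window from 144530001 on the plus strand of chromosome 6 was listed with both constructs, at 5608 ± 484.6 and 1435 ± 163.1 ppm, 3.91 times as much (log2 difference 1.97 ± 0.38 SE, limma adjusted p = 0.0488). Both 226del783 libraries are of the later series, and with the series as a block 10 of the 14 windows passed, without this last one (adjusted p = 0.0674, limma). Of the 14 windows, 8 were also listed in a control, and some of these held more there than in full-length 4SU libraries. Without antibody the window from 144530001 held 7181 ± 6539 ppm (SD, n = 2), and that from 61870001 held 4012 ± 3865, against 1316 ± 1040 for full-length CDK11. At 73510001 it was the other way, with 639.4 ± 904.2 against 1416 ± 1061. These control values rest on 11, 6 and 2 cDNAs. For such windows a higher full-length share does not by itself show CDK11 contacts. The chromosome X window from 107970001 did not pass here, with 14519 and 35855 ppm for 226del783 and 3260 and 17925 for full-length CDK11. With lists limited to the same number of sites, 30 windows were higher and 12 lower, 12 of them shared with the 14; the window from 26190001 no longer passed (log2 difference 3.54 ± 3.35 SE, limma adjusted p = 0.552). The count was 0 without full-length 4SU replicate 1, 3 without its replicate 2, and 112 without 226del783 replicate 1.

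The crosslinking methods were compared in full-length CDK11. With 4SU and 365 nm the lists were 2.11 times as long as at 254 nm (2 against 2 libraries, exact permutation test, p = 0.333, the smallest it allows). The ratio was 3.07 in the earlier and 1.45 in the later series, 1.21 without full-length 4SU replicate 1 and 3.68 without its replicate 2. Contig GL000220 held 13.5% ± 8.13 (SD, n = 2) of the cDNAs at 254 nm and 2.31% ± 0.551 with 4SU, the mitochondrial chromosome 17.1% ± 0.558 and 8.73% ± 2.56, and chromosome 6 from 26 to 28 Mb 4.56% ± 2.13 and 10.1% ± 1.17. The 1del226 libraries had 14.1% ± 12.2 and 1.76% ± 0.390 on contig GL000220, 9.10% ± 2.39 and 7.81% ± 3.54 on the mitochondrial chromosome, and 5.89% ± 1.16 and 9.63% ± 2.29 on the chromosome 6 interval, in the same order of methods.

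Between methods, 5 windows were higher with 4SU and 1 was lower (limma, adjusted p under 0.05). The plus strand of chromosome 17, 19410001 to 19420000, held 2884 ± 967.5 ppm with 4SU and 73.6 ± 0.38 at 254 nm, 39.2 times as much (SD, n = 2; limma adjusted p = 0.0465). The minus strand of the same chromosome, 8120001 to 8130000, held 6111 ± 971.3 and 385.3 ± 169.1, the minus strand of chromosome 1, 145390001 to 145400000, held 9713 ± 685.1 and 1316 ± 122.3, and the plus strand of chromosome 2, 27270001 to 27280000, held 8737 ± 673.8 and 1619 ± 243.7. The plus strand of chromosome 19 from 10220001 was listed with 4SU only (1197 ± 906.4), and contig GL000229 from 10001 (plus) at 254 nm only (1790 ± 746.5), both within full-length lists. With the replicate block the count was 50, with 44 higher and 6 lower, and with lists limited to the same number of sites it was 69, with 45 higher and 24 lower. Fits that left out 1 of these libraries, and so left 1 library in a group, lost all or nearly all of the 6 calls.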

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

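Full-length lists stayed longer than control lists under every alternative run, by 27.6 to 81.5-fold across site definitions and 34.7 to 58.7-fold with each library left out; the exact permutation p stayed at 0.0286 except with the replicate block (47.3-fold, exact permutation p = 0.0556, the smallest possible). They stayed longer than 1del226 lists by 3.44 to 5.56-fold, and by 4.08 to 7.71-fold with each library left out; the exact permutation p was 0.0286 when labels moved over all 8 libraries (5.56-fold) and 0.125 with the replicate block. The difference in chromosome 6 from 26 to 28 Mb changed sign to 0.543 percentage points with at least 5 cDNAs per site and to 0.301 in lists of the same number of sites, was -3.52 by share of sites (5.63% against 9.15%, exact permutation p = 0.111), and ranged from -1.64 to 0.973 with each library left out (positive without full-length 254 nm replicate 2 and, at 0.717, without 1del226 4SU replicate 1); the cause was not tested. Shares of sites within 5 nt moved with the distance and the minimum of 5 cDNAs; at 0 nt they were 33.3% and 43.5% between the 2 full-length lists of 254 nm and of 4SU.

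Counts of windows depended strongly on the setting. For full-length against 1del226 the 20 windows became 1 with no filter (19193 windows tested), 42 with only the 8 libraries, 42 without the mitochondrial chromosome and contig GL000220, 71 with windows of 100 kb, 6 with at least 5 cDNAs per site, 0 in lists of the same number of sites, and 0 to 42 with each library left out. With the replicate block they were 28, which included the 20. For full-length against 226del783 the 14 became 0 with no filter, 0 with a pseudocount of 100 ppm, 24 with at least 5 cDNAs, 42 in lists of the same number of sites and 0 to 112 with each library left out. For 4SU against 254 nm the 6 became 0 with no filter, 0 with windows of 1 kb, 12 without the mitochondrial chromosome and contig GL000220, 20 with windows of 100 kb, 50 with the replicate block, 54 with a pseudocount of 100, 69 in lists of the same number of sites and 0 to 13 with each library left out. With no filter the loss goes with the number of windows tested; for the others the cause was not tested. The interaction gave 0 windows throughout. With the replicate block full-length against 226del783 gave 16, 13 of them shared with the 14; it changed no call beyond those given here. The experiment series as a block gave 18 of the 20, 10 of the 14, and 9 with the 6 among them. With each library left out, of the named windows only those from 34210001 (plus) and 74220001 on chromosome 6 and from 217360001 on chromosome 2, for full-length against 1del226, passed in every fit that tested them (4, 5 and 6 of 8). In the other fits these windows missed the filter. For the window from 34210001 the 4 fits all left out a 1del226 library, so the loss of a full-length library was never tested. With no filter that window did not pass (adjusted p = 0.225, limma). Of the alternative values of the named windows 219 passed as before and 156 did not; most have an empty lower group, so their direction could not turn. For the chromosome 6 window from 26150001 the adjusted p ranged from 0.0122 to 0.248, and missed the threshold with no filter (0.248), with at least 5 cDNAs (0.248), in lists of the same number of sites (0.101), and without any 1 of the 4 full-length libraries or 1del226 4SU replicate 2. Another tool and scaling for counts were not run because the signed scores were not entered as counts. The sign itself did not prevent such a run, since the sizes were read as numbers of cDNAs. The alternatives of the gene-level, histone, intron and gene list results were not run for want of an annotation. The filter, the series block, the pseudocount of 100, the scaling and the minimum of 5 cDNAs in windows were added after seeing the data.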

Other observations

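Fits of windows in lists of the same number of sites were set before the data were seen. The other tests with such lists and the reading of those fits, the tests of the no-UV share, the count of splits and the comparison of compact windows were chosen after their results were seen, as were the regions themselves. The test on chromosome 1 and the test of dilution were set before theirs.

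Within the interval from 26 to 28 Mb of chromosome 6, the windows did not move together. The part from 26000001 to 26260000, where the first group of genes of the main histone cluster is known to lie, held 1.17% ± 0.602 of the cDNAs in full-length libraries (SD, n = 4) and 0.227% ± 0.125 for 1del226 (n = 4). With 4SU alone it was 0.936% ± 0.052 for full-length CDK11 (n = 2), 0.900% in its later-series library, and 0.294% and 0.720% in the later-series 226del783 libraries. Against 1del226 it was higher in full-length libraries in 4 of 4 pairs (difference 0.946 percentage points, exact permutation within method, p = 0.0556, the smallest the design allows; replicate block, p = 0.125). By share of sites it was higher in 3 of 4 pairs (exact permutation, p = 0.167). The no-UV lists held no cDNA there (upper Wilson 95% bounds 0.0588% and 0.188%, for counting error only and listed sites only), and the no-antibody lists held 3 of 1564 cDNAs and none.

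For this region, 3 technical explanations were set against a difference of the construct. Longer lists could raise the share, but in lists of the same number of sites it was still higher in 4 of 4 pairs, at 0.840% ± 0.584 against 0.139% ± 0.035. Such a cut keeps the tallest sites and does not repeat the peak test at a lower depth, so it cannot exclude list length. Within 1del226 the longest list had the highest share, 0.411%, against 0.136% to 0.190% in the others. Among full-length lists the longest had 0.973%, within a range from 0.752% to 2.065%. Signal that does not need UV would appear without UV, and the highest no-UV share was 0 (0.0%), below the lowest full-length share of 0.752%. Dilution of the 1del226 lists by such signal would lower other UV-dependent windows as much. The 460 other windows with a site in every full-length library and in no control were pooled. Their folds were 1.54, 1.99, 1.20 and 2.01 in the 4 pairs, and the region had 12.2, 5.53, 2.37 and 4.75, higher in 4 of 4. But the region was chosen after its values were seen, and that choice alone can place it above a pooled fold. The spread of the folds of single windows was not compared, so this test cannot decide about dilution. A candidate explanation is that RNAs of histone genes carry a larger share of the full-length sites; the part of chromosome 1 from 149780001 to 149870000, where a further histone gene cluster is known to lie, was higher in full-length libraries in 4 of 4 pairs, at 0.143% ± 0.033 against 0.0236% ± 0.0271 (exact permutation, p = 0.0556, the smallest possible), but in 3 of 4 pairs by share of sites (p = 0.167), in 2 of 4 with at least 5 cDNAs per site (p = 0.5) and in 2 of 4 in lists of the same number of sites (p = 0.278). It stays a hypothesis, since no site was assigned to a gene and since it was found and tested on the same data.

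Of the 16 windows described as higher in full-length libraries, 15 lacked a site in at least 1 1del226 library and may reflect list length. In lists of the same number of sites 10 of the 15 still had a site in more full-length than 1del226 libraries, and the others had none. The bound written against list length, more than 0.5 of the windows, was met, but it was a wrong bound, because 12 of the 15 have no site in the whole 1del226 lists and could not move the other way. That reading was set after the value was seen, and list length cannot be told apart from a difference of the construct for these 15. Against list length, 9 of the 15 had a site in both 226del783 lists (15190 and 4865 sites), and the chromosome X window from 107970001 had 1231 cDNAs there and 1 in the 4 1del226 lists. Of all 660 windows with a site in the 4 full-length libraries, 214 had a site in both 226del783 lists and 135 had none for 1del226. The shorter 226del783 list held 8334 cDNAs, fewer than each of the 4 1del226 lists (13189 to 105276). It also had fewer sites than the 1del226 lists of 5209 and 15018 sites. The other way, 5 of the 15 windows had no site in either 226del783 list. List length stays open because the 226del783 shares could be higher in their own right. The chromosome 6 window from 26150001, with a site in all 8 libraries, did not fall in lists of the same number of sites. Its log2 difference was 3.68 ± 0.63 (SE) against 3.37 ± 0.57 before, and the 4 full-length shares lay above the 4 1del226 shares. The cut to the tallest sites does not repeat the peak test at a lower depth, so list length is not excluded there. In lists of the same number of sites the chromosome X window from 107970001 held 5535 ppm in full-length libraries and none for 1del226, in 2 of 4 full-length libraries. Chance was not excluded by the count of splits alone: of the 35 ways to split the 8 libraries, 2 gave at least as many windows as the 26 of the real split (fitted without crosslinking method). The other was the split by crosslinking method, with 116, which points to a structure of the libraries by method. All remaining splits gave 0, the split by experiment series among them. They mix the constructs, as do the 7 among them that part all 4 pairs of same-numbered full-length and 1del226 libraries.

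The 3 windows lower in full-length libraries may hold signal that does not need UV. Together they held a mean of 35.1% of the cDNAs of a no-UV library (20.0% in replicate 1 and 50.2% in replicate 2; 2329 of the 8565 cDNAs of both), and each had a higher share in both no-UV libraries than in any full-length library. Their numbers of cDNAs were similar in full-length and 1del226 libraries, with ratios of 0.687, 0.576, 1.19 and 0.905 in the 4 pairs, while the list totals had ratios of 4.52, 3.41, 3.96 and 6.27. A fixed amount of such signal in lists of unequal totals is consistent with this. The no-antibody lists held 0.497%, 0.613% and 0.887% in the windows on chromosomes 17, 15 and 6, and a difference of the construct stays open.

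Whether sites were more compact depended on list length. Among 10-kb windows with at least 10 cDNAs outside the mitochondrial chromosome and contig GL000220, those whose sites span at most 150 nt held 72.8% ± 7.52 of the cDNAs for 1del226 (SD, n = 4) and 58.1% ± 5.22 for full-length CDK11 (exact permutation, p = 0.0556, the smallest possible), but 73.5% ± 7.18 and 74.9% ± 5.98 in lists of the same number of sites (p = 0.389). For 226del783 the shares were 46.9% ± 4.87 (n = 2) and 56.0% ± 1.20.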
